A study of Mus musculus with 24 samples.

How the data were processed

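Bulk RNA-seq was read from 24 mouse libraries of Lin-Sca1+KIT+ (LSK) progenitors, 4 in each of 6 groups. The groups cross 3 ages with control cells and cells carrying the Tet-On MLL::ENL (ME) transgene, and groups were taken from the sample titles. The E16 cells came from liver and the P14 and 8wk cells from bone marrow, per the labels, so age and tissue cannot be separated at E16. Total RNA was extracted with an RNeasy Plus kit and libraries were made with a Clontech SMART-type kit, per the labels' protocols. Nothing in the labels says whether replicates were separate animals; if they were not, the p-values measure the spread between these samples, which may be technical.

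The deposited values were raw counts per Ensembl gene, 1 column per library. The authors aligned reads with STAR 2.7.9a to GRCm38 and counted them with featureCounts 2.0.3 of Subread, per the submitters' processing notes. The annotation release, the strand setting and any filter were not stated. Among counts from 1 to 20, a median of 63.6% per library were even, as when both mates of a pair are counted. If so, counts are not independent, and counting intervals here are too narrow and floors of fold changes too high. The 55774 lines held 55487 unique Ensembl identifiers; 168 identifiers stood on several lines with identical counts and were kept once. Of these identifiers, 55141 were in GENCODE M21, which gave coordinates and transcript GC content. Symbols and biotypes were those of the deposited file. Counts of near-identical genes (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, the Stfa and Cstdc genes, the H2-Q genes) and of genes that overlap on opposite strands are uncertain without the strand setting.

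Library totals ranged from 33.9 to 69.3 M counts, with a median of 47.1 M. The number of genes with at least 1 count per library ranged from 22259 to 25501. Values far below 1 CPM rest on few counts. Where a group held 0 counts of a named gene over its 4 libraries, the fold is a lower bound computed at a floor of 3 counts over the group. Where it held 1 to 3 counts, the ratio of pooled CPM is given with its 95% counting interval.

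Genes were filtered with filterByExpr (minimum count 10), which left 18931 genes. All 24 libraries were fitted together with TMM factors and the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with 1 mean per group. The 9 comparisons were ME against control at each of 3 ages, the 3 differences between these ME effects, and the 3 pairs of control ages. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Standard errors are those of the edgeR log2 fold changes. CPM values use TMM-scaled library sizes, and their errors are SD over 4 libraries. The edgeR fit and test and camera were run on simulated data with known changes, while the alternatives, the splits and the later tests were not. The simulated libraries were drawn independently, with no pairs and no library apart from its group. In the simulated E16 comparison on 18469 genes, 43 of 97 genes changed 2-fold and 80 of 99 changed 4-fold were called, with 11 false calls among 18273 unchanged genes. In the simulated difference of 8wk and E16 effects, 21 of 97 and 61 of 99 were called, with 5 false calls. With no simulated change between control P14 and E16, 0 genes were called.

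Before the data were examined, 24 gene lists, the comparisons, a first set of alternative settings and the rule for named genes were written down. The lists were MLL fusion targets, Hoxb genes, HSC markers, B-lineage genes, Lymphoid-primed progenitor genes, T and NK cell markers, Granulocyte-monocyte progenitor genes, Mature neutrophil markers, Monocyte and macrophage markers, Dendritic cell and MHC class II genes, Erythroid genes, Megakaryocyte genes, Mast cell, basophil and eosinophil markers, Fetal progenitor genes, Type I interferon response genes, Cell cycle genes, Myc and ribosome biogenesis genes, p53 target genes, Polycomb genes, Immediate early and heat shock genes, Hepatocyte markers, Endothelial markers, Stromal markers and Sex-linked genes. Lists were tested against all other genes with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 24 lists. Each was also tested with an estimated correlation. Member counts are given over all genes tested and adjusted over the list alone.

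The rule always named Kmt2a, Mllt1 and Skida1. For each ME comparison it named the 8 largest rises and the 8 largest falls among called genes with at least 5 CPM in the higher group and all 4 libraries of 1 group above all 4 of the other. For control ages it named 6 in each direction on the same terms. For differences of ME effects it named 6 in each direction, without the overlap condition and with at least 5 CPM in the highest of the groups involved. Clone-type symbols were passed over. It also named up to 4 members with the smallest adjusted p of each list with a called member. Genes outside the rule are marked as chosen after their values were seen.

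The first set of alternatives was DESeq2 size factors, library size only, no filter beyond 1 count, at least 1 CPM in 4 libraries, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, a Y-linked covariate, the replicate number as a block, only the libraries of the 2 groups compared, an added limit of a log2 fold change over 1, an estimated correlation, and leaving out each library in turn. After seeing the data, 4 alternatives were added: a correction for transcript GC content (loess, span 0.3), that correction with the replicate block, protein-coding genes only, and leaving out 3 libraries that stand apart (E16_ME replicate 4, 8wk_ME replicate 4 and 8wk_Control replicate 1). To see whether replicate numbers pair ME and control libraries, residuals were correlated between equal numbers. At P14 all 4 correlations were above 0.1, from 0.137 to 0.232, and 2 of 4 libraries matched their own number best. At E16 they ran from -0.0434 to 0.000655 and at 8wk from -0.0882 to 0.118. The highest P14 correlation, 0.242, was between unlike numbers. Controls of E16 and 8wk, which differ in age, ran from 0.0392 to 0.270 at equal numbers, with 2 of 4 best at their own. Pairing at P14 is therefore possible but not shown. The block is given beside results of P14 ME effects where it changes a call or moves a count by over 1.5 times, and otherwise only with the other alternatives. No library or assigned sample was left out of the comparisons as designed.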

Results

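RNA-seq was done on 24 libraries of LSK cells, the mouse compartment that holds blood stem cells and multipotent progenitors. ME cells carried an inducible (Tet-On) MLL::ENL, a leukaemia fusion of MLL (Kmt2a) with ENL (Mllt1), and were compared with control cells after 48 h of culture. Each of the 6 groups held 4 libraries. Mean totals were 46.7 M counts in E16 ME, 44.3 in E16 control, 43.5 in P14 ME, 60.2 in P14 control, 46.5 in 8wk ME and 55.5 in 8wk control. Exact two-sided permutation tests of totals between ME and control gave p = 0.714 at E16, 0.0857 at P14 and 0.257 at 8wk (adjusted p = 0.714, 0.257 and 0.386), where 0.0286 is the smallest p that 4 against 4 can give. The same permutation tests of the ribosomal RNA share gave p = 0.971, 0.543 and 0.657, with an adjusted p of 0.971 for each. The first 3 principal components of the tested genes carried 29.2%, 21.8% and 10.2% of the variance. The 3 libraries that stand apart were chosen after the data were seen. They differ in myeloid markers, so results of myeloid lists without them are not given. Groups mixed male and female material unevenly, judged from Xist and Y-linked genes. Of the 8wk controls only replicate 1 was mainly male (Y-linked genes 237 CPM). Of 5 Sex-linked genes edgeR called 0 in any ME comparison (adjusted p of the list = 0.616, 0.804 and 0.732). Mixed groups widen the spread, so this shows no balance.

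**Figure D1:**
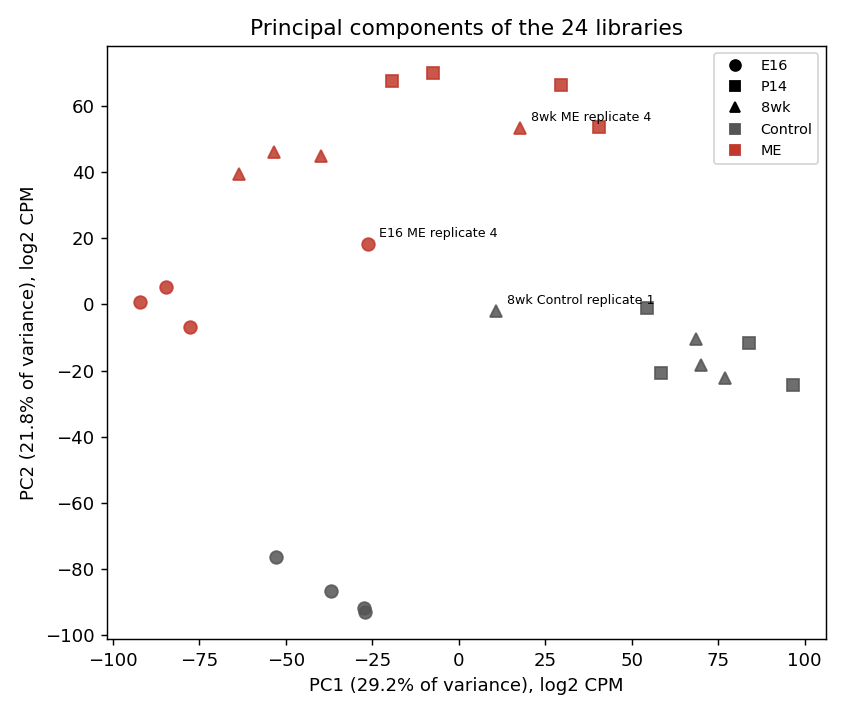
Principal components 1 (29.2% of the variance) and 2 (21.8%) of the 24 libraries, 1 point per library, coloured by age and genotype. The 3 libraries that stand apart from their groups are labelled.

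The E16 comparison asked what MLL::ENL changed in fetal liver progenitors. Skida1 (ENSMUSG00000054074, GRCm38 chromosome 2, 18040676 to 18049051), the gene named in the series title, rose from 0.646 ± 0.190 to 13.5 ± 2.21 CPM (SD, n = 4 per group), a log2 fold change of 4.39 ± 0.31 (SE; edgeR adjusted p = 4.24e-09). Mllt1 (ENSMUSG00000024212, chromosome 17, 56892611 to 56935415), the ENL gene, rose by 1.54 ± 0.29 log2 from 18.4 ± 6.01 CPM (adjusted p = 6.00e-04). Kmt2a (ENSMUSG00000002028, chromosome 9, 44803355 to 44881296), the MLL gene, rose by 0.85 ± 0.23 log2 from 9.74 ± 2.40 CPM (adjusted p = 0.00946). All 4 ME libraries lay above all 4 control libraries for each of the 3 genes. Counts per gene cannot separate reads of the fusion from reads of the endogenous Mllt1 and Kmt2a genes.

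Among the genes of 5 CPM or more with the largest rises at E16, Cdh2, the adhesion protein N-cadherin, rose from 0.715 ± 0.156 to 46.0 ± 11.8 CPM (SD, n = 4), a log2 fold change of 6.01 ± 0.38 (SE; adjusted p = 1.33e-09). Il9r, the interleukin 9 receptor, rose by 5.79 ± 0.37 log2 to 34.1 ± 8.63 CPM (adjusted p = 1.33e-09). Src, a tyrosine kinase, rose by 5.09 ± 0.47 log2 and Plch2, a phospholipase C, by 10.01 ± 1.21 log2. Genes of platelets were among those that fell. Ppbp, a platelet chemokine, fell from 138 ± 82.6 to 2.30 ± 2.03 CPM, a log2 fold change of -5.89 ± 0.95 (adjusted p = 1.96e-04). Alox12, the platelet lipoxygenase, changed by -3.55 ± 0.41 log2 (adjusted p = 3.61e-06), and Tubb1, the platelet tubulin, by -3.59 ± 0.70 log2. Over all 18931 genes tested, edgeR called 2522 higher and 1603 lower in ME. The share of higher genes was 61.1%, against 74.6% with library size only and 36.2% after GC correction.

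Of 24 tested MLL fusion targets at E16, 15 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 3.82e-16, and 0.00859 with an estimated correlation). Nkx2-3, a homeobox factor, rose by 4.38 ± 0.30 log2 to 18.7 ± 4.00 CPM (SD, n = 4), and Hoxa10 rose by 2.12 ± 0.16 log2 from 12.4 ± 1.31 to 53.6 ± 8.68 CPM. The member that fell was Cdk6, a cell cycle kinase, at -0.41 ± 0.13 log2 (adjusted p = 0.0298), named after its value was seen. Of 5 Hoxb genes 4 rose (4 over the list alone; adjusted p = 9.69e-04, and 0.0175 with an estimated correlation), with Hoxb5 at 2.66 ± 0.40 log2. Of 16 Polycomb genes 5 rose and 0 fell (6 and 0 over the list alone; adjusted p = 0.00780, and 0.0372 with an estimated correlation). Bmi1 and Suz12, subunits of Polycomb complexes, rose by 1.85 ± 0.24 and 1.87 ± 0.34 log2. Of 20 Myc and ribosome biogenesis genes 19 fell (19 over the list alone; adjusted p = 3.36e-13, and 0.0175 with an estimated correlation). Myc itself went from 488 ± 43.7 to 278 ± 24.0 CPM, -0.81 ± 0.13 log2. The member that rose was Odc1, the polyamine enzyme, at 2.07 ± 0.41 log2 (adjusted p = 0.00124), named after its value was seen.

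The other list calls at E16 were lost with an estimated correlation. Of 16 HSC markers 8 rose and 1 fell (10 and 2 over the list alone; adjusted p = 0.00173, and 0.588 with an estimated correlation). Procr, the stem cell marker EPCR, rose by 1.48 ± 0.24 log2 and Cdkn1c, the cell cycle inhibitor p57, by 3.44 ± 0.60 log2 (SE, n = 4 per group), while Slamf1, named after its value was seen, fell at -1.43 ± 0.43 log2. Of 20 B-lineage genes 6 rose and 0 fell (6 over the list alone; adjusted p = 0.00632, and 0.650 with an estimated correlation). Rag2 and Rag1, which recombine antigen receptor genes, rose by 1.61 ± 0.29 and 1.99 ± 0.44 log2, and Bach2, a lymphoid transcription factor, by 2.17 ± 0.45 log2. Of 12 Megakaryocyte genes 9 fell (9 over the list alone; adjusted p = 2.96e-07, and 0.167 with an estimated correlation), Gp1ba, a platelet adhesion receptor subunit, at -2.62 ± 0.44 log2. Of 13 Mast cell, basophil and eosinophil markers 2 fell (2 over the list alone; adjusted p = 0.00780, and 0.649 with an estimated correlation), the basophil protease Mcpt8 at -2.53 ± 0.36 log2. Of 30 Type I interferon response genes 10 rose (15 over the list alone; adjusted p = 3.93e-04, and 0.649 with an estimated correlation), and 4 rose without the 3 libraries that stand apart (adjusted p = 0.0136). Of 26 Cell cycle genes 12 fell and 1, the transcription factor E2f1 at 2.00 ± 0.46 log2, rose (16 and 2 over the list alone; adjusted p = 9.30e-05, and 0.371 with an estimated correlation).

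Calls of 2 further lists at E16 were also lost on leaving out libraries. Of 15 Lymphoid-primed progenitor genes 5 rose (5 over the list alone; adjusted p = 0.0359, and 0.588 with an estimated correlation), with the chromatin organiser Satb1 at 1.98 ± 0.21 log2 (SE, n = 4 per group). That list's adjusted p was 0.0506 without E16_ME replicate 3, 0.0744 without E16_Control replicate 4, 0.0727 with the Y-linked covariate and 0.0878 without the 3 libraries that stand apart. Of 14 Mature neutrophil markers 1 fell (1 over the list alone; adjusted p = 0.00842, 0.668 with an estimated correlation, and 0.0506 without E16_ME replicate 4). That member was Ltf, the granule protein lactoferrin, at -3.34 ± 0.94 log2. The remaining lists were not called at E16. Endothelial markers (3 of 9 higher; Emcn 2.05 ± 0.27 log2) had an adjusted p of 0.0603, and were called with at least 1 CPM in 4 libraries (0.0419) or only the 2 groups (0.0216) or without E16_ME replicates 1 and 2 (0.0229 and 0.0435) or E16_Control replicate 2 (0.0327). The adjusted p was 0.369 for Granulocyte-monocyte progenitor genes (2 of 16 higher, among them the repressor Gfi1 at 4.02 ± 0.67 log2, and 2 lower), 0.738 for T and NK cell markers (1 of 14 higher) and 0.616 for Monocyte and macrophage markers (1 of 17 higher, with a positive median and a downward test). It was 0.283 for Dendritic cell and MHC class II genes (0 of 13 called), 0.479 for Erythroid genes (2 of 18 lower), 0.641 for Fetal progenitor genes (1 of 14 higher, 2 lower) and 0.479 for p53 target genes (3 of 18 higher, 3 lower). It was 0.704 for Immediate early and heat shock genes (3 of 13 higher, 1 lower), 0.683 for Hepatocyte markers (0 of 3) and 0.759 for Stromal markers (0 of 5).

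**Figure D2:**
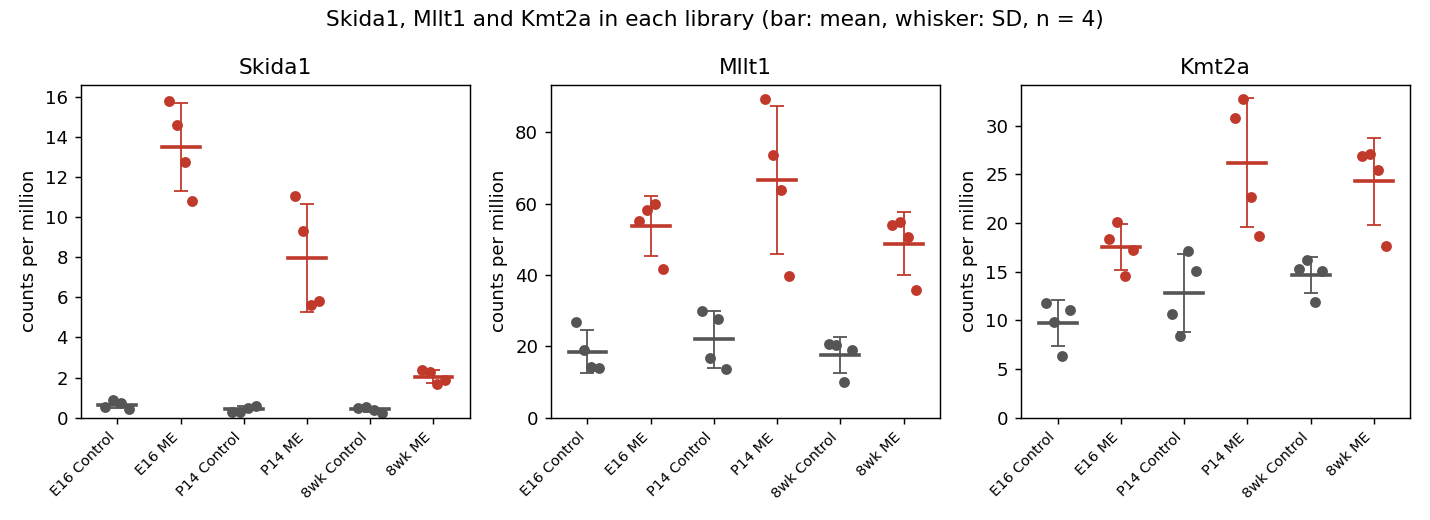
Skida1, Mllt1 and Kmt2a in CPM in each of the 24 libraries, by age and genotype, with the mean as a bar and the SD (n = 4) as a whisker. At each age the 4 ME libraries lie above the 4 controls for each gene.

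The P14 comparison asked the same of neonatal bone marrow progenitors. Skida1 rose from 0.403 ± 0.150 to 7.96 ± 2.7 CPM (SD, n = 4 per group), a log2 fold change of 4.29 ± 0.31 (SE; edgeR adjusted p = 5.67e-09). Mllt1 rose by 1.60 ± 0.29 log2 from 22.0 ± 7.99 CPM (adjusted p = 3.60e-04), and Kmt2a by 1.03 ± 0.23 log2 from 12.8 ± 4.00 CPM (adjusted p = 0.00212). Il9r rose by 7.31 ± 0.41 log2 to 26.6 ± 3.46 CPM, Cdh2 by 6.77 ± 0.40 log2 to 25.8 ± 3.72 CPM and Amigo2, an adhesion protein, by 4.73 ± 0.61 log2. Plch2, with 2 counts over the 4 controls, was higher by a ratio of 729 (95% counting interval 201 to 6029, if counts are independent). Genes that fell included Lvrn, an aminopeptidase, at -3.99 ± 0.59 log2, Gzmb, granzyme B, at -3.86 ± 0.84 log2, and Dlk1, an imprinted surface protein, at -2.45 ± 0.40 log2 from 58.2 ± 12.9 CPM. In each of these genes all 4 libraries of 1 group lay above all 4 of the other. Over all genes 2398 were higher and 1770 lower in ME (57.5% higher, against 70.5% with library size only and 32.3% after GC correction with its re-centring).

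Of 20 tested B-lineage genes at P14, 16 rose and 0 fell (17 over the list alone; camera adjusted p = 7.87e-04, and 0.686 with an estimated correlation). Rag2 rose by 1.84 ± 0.29 log2 from 4.48 ± 2.03 to 16.1 ± 5.32 CPM (SD, n = 4), in all 4 libraries. Cd79a, a signalling chain of the B cell receptor, rose by 5.09 ± 1.17 log2, with an SD above the mean in ME (26.2 ± 35.8 CPM). It stood at 76.8 and 26.3 CPM in P14_ME replicates 1 and 2 (female) and at 1.41 and 0.207 in replicates 3 and 4 (male). Controls were at 0.0844 to 1.38. With limma-voom Cd79a had an adjusted p of 0.123, and 0.0603 with only the P14 libraries. The list's adjusted p was 0.0519 without P14_ME replicate 1 and 0.0521 with only the P14 libraries.

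Of 24 MLL fusion targets at P14, 14 rose and 0 fell (16 over the list alone; adjusted p = 1.13e-14, and 0.0153 with an estimated correlation). Nkx2-3 rose by 4.73 ± 0.30 log2 to 27.4 ± 7.36 CPM (SD, n = 4), and Hoxa10 by 2.22 ± 0.16 log2 to 72.2 ± 12.3 CPM. Of 16 Polycomb genes 6 rose and 0 fell (7 over the list alone; adjusted p = 0.00813, and 0.0400 with an estimated correlation), with Bmi1 at 2.08 ± 0.24 log2. Of 20 Myc and ribosome biogenesis genes 16 fell and 1, again Odc1 at 2.36 ± 0.42 log2, rose (17 and 1 over the list alone; adjusted p = 1.10e-10, and 0.0400 with an estimated correlation). Polr1b, an RNA polymerase I subunit, fell at -0.83 ± 0.10 log2. Of 30 Type I interferon response genes 22 rose (27 over the list alone; adjusted p = 1.13e-14, and 0.189 with an estimated correlation). The transcription factor Irf9 rose by 1.00 ± 0.12 log2 and the antiviral enzyme Rsad2 by 2.35 ± 0.31 log2 from 2.07 ± 0.279 CPM. Of 26 Cell cycle genes 16 fell and 1, E2f1 at 2.53 ± 0.47 log2, rose (20 and 2 over the list alone; adjusted p = 6.64e-08, and 0.187 with an estimated correlation). Cdc20, an activator of mitotic exit, fell at -0.70 ± 0.11 log2.

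Of 15 Lymphoid-primed progenitor genes at P14, 5 rose (5 over the list alone; adjusted p = 0.0360, and 0.618 with an estimated correlation), with Satb1 at 1.88 ± 0.21 log2 (SE, n = 4 per group) and the transcription factor Foxo1 at 2.74 ± 0.55 log2. That list's adjusted p was 0.128 and 0.0892 without P14_ME replicates 1 and 2, 0.0514 and 0.0509 without P14_Control replicates 1 and 2, 0.0531 with at least 1 CPM in 4 libraries, 0.123 with only the P14 libraries and 0.0665 without the 3 libraries that stand apart. The other lists were not called. Monocyte and macrophage markers (5 of 17 higher, 7 over the list alone) had an adjusted p of 0.0935, which became 0.0430 with the replicate block, 0.00767 with no filter, 0.0174 and 0.0242 without P14_ME replicates 3 and 4, and 0.0368 without P14_Control replicate 2. C1qb, a complement subunit of macrophages, was at least 74.6-fold higher, since it had 0 counts over the controls. Hoxb genes (1 of 5 higher) had an adjusted p of 0.0866, called with no filter (0.0279) and without P14_ME replicate 3 (0.0339), P14_Control replicate 1 (0.0489) or P14_Control replicate 4 (0.0465). HSC markers (5 of 16 higher, 2 lower) had 0.159, called with no filter (0.0383) and with only the P14 libraries (0.0119).

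At P14 the remaining adjusted p values were 0.594 for T and NK cell markers (4 of 14 higher, 1 lower), 0.927 for Granulocyte-monocyte progenitor genes (2 of 16 higher, with Gfi1 at 4.69 ± 0.69 log2 and Cebpa, a myeloid transcription factor, at 2.44 ± 0.58 log2) and 0.452 for Mature neutrophil markers (0 of 14 called). The Granulocyte-monocyte progenitor genes had a positive median and a downward test, as did the Mast cell, basophil and eosinophil markers (1 of 13 higher, 2 lower; adjusted p = 0.548). The adjusted p was 0.452 for Dendritic cell and MHC class II genes (1 of 13 higher), 0.899 for Erythroid genes (1 of 18 higher, 1 lower), 0.336 for Megakaryocyte genes (1 of 12 higher) and 0.452 for Fetal progenitor genes (2 of 14 higher, 2 lower; median above and mean below 0). It was 0.281 for p53 target genes (1 of 18 higher, 4 lower), 0.273 for Immediate early and heat shock genes (1 of 13 higher, 1 lower), 0.336 for Hepatocyte markers (0 of 3), 0.336 for Endothelial markers (2 of 9 higher) and 0.574 for Stromal markers (0 of 5; median above and mean below 0).

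The 8wk comparison asked the same of adult bone marrow progenitors. Skida1 rose from 0.411 ± 0.135 to 2.03 ± 0.331 CPM (SD, n = 4 per group), a log2 fold change of 2.30 ± 0.30 (SE; edgeR adjusted p = 1.45e-05). Mllt1 rose by 1.48 ± 0.29 log2 from 17.5 ± 5.12 CPM (adjusted p = 7.25e-04). Kmt2a rose by 0.73 ± 0.23 log2 from 14.6 ± 1.86 CPM (adjusted p = 0.0183). Its adjusted p was 0.0529 without 8wk_ME replicate 2 and 0.0598 without 8wk_Control replicate 3. Il9r rose by 7.05 ± 0.41 log2 to 21.0 ± 7.97 CPM (adjusted p = 1.65e-10). Cdh2 stood at 12.7 ± 2.38 CPM in ME, with 2 counts over the 4 controls, a ratio of 1353 (95% counting interval 374 to 11178). Car4, a carbonic anhydrase, was at least 2029-fold higher against 0 counts in the controls, though 8wk_ME replicate 4 held 0.669 CPM and the other ME libraries 28.6 to 46.2. The chemokine gene Ccl2 rose by 5.78 ± 1.08 log2. Gzmb fell from 63.6 ± 36.3 to 1.90 ± 1.62 CPM (-5.06 ± 0.88 log2), the amino acid transporter Slc6a15 fell at -2.86 ± 0.30 log2 and Mcpt8 at -1.97 ± 0.35 log2. Over all genes 2684 were higher and 2708 lower in ME (49.8% higher, against 33.5% after GC correction). The total of 5392 became 3433 without 8wk_Control replicate 3 and 2907 with only the 8wk libraries.

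Myeloid marker lists rose at 8wk, and each call was lost with an estimated correlation. Of 17 Monocyte and macrophage markers 9 rose (9 over the list alone; adjusted p = 2.32e-04, and 0.368 with an estimated correlation). Cd14, the endotoxin co-receptor, rose by 5.21 ± 0.91 log2 to 71.1 ± 57.0 CPM (SD, n = 4), from 6.98 CPM in 8wk_ME replicate 4 to 145 in replicate 1. Of 16 Granulocyte-monocyte progenitor genes 3 rose (3 over the list alone; adjusted p = 0.00220). Gfi1 rose by 4.20 ± 0.68 log2 and Cebpa by 2.88 ± 0.59 log2. Of 14 Mature neutrophil markers 1, the integrin Itgam at 2.59 ± 0.58 log2, rose (1 over the list alone; adjusted p = 0.0144). Of 13 Dendritic cell and MHC class II genes 2 rose (2 over the list alone; adjusted p = 0.00997). Cd74, the invariant chain of MHC class II, rose by 2.27 ± 0.53 log2.

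Of 18 p53 target genes at 8wk, 11 rose and 1 fell (14 and 1 over the list alone; adjusted p = 7.57e-05, and 0.296 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose by 2.21 ± 0.44 log2 from 28.8 ± 24.3 to 134 ± 67.6 CPM (SD, n = 4), with 58.2 CPM in 8wk_ME replicate 4 and 65.1 in 8wk_Control replicate 1. Pmaip1, the apoptosis gene Noxa, rose by 2.02 ± 0.38 log2, and the member that fell was Perp at -1.17 ± 0.29 log2, named after its value was seen. Of 24 MLL fusion targets 13 rose and 0 fell (15 over the list alone; adjusted p = 1.44e-06, and 0.173 with an estimated correlation), with Nkx2-3 at 3.89 ± 0.29 log2 and Hoxa10 at 0.97 ± 0.15 log2. Of 30 Type I interferon response genes 25 rose (28 over the list alone; adjusted p = 9.60e-16, and 0.233 with an estimated correlation), with Rsad2 at 2.31 ± 0.31 log2 and Irf9 at 0.84 ± 0.12 log2. Of 20 Myc and ribosome biogenesis genes 16 fell and Odc1 rose by 2.31 ± 0.42 log2 (16 and 1 over the list alone; adjusted p = 3.39e-09, and 0.173 with an estimated correlation). The nucleolar protein gene Npm1 went from 1348 ± 282 to 731 ± 66.3 CPM. Of 26 Cell cycle genes 13 fell and E2f1 rose by 2.57 ± 0.47 log2 (15 and 1 over the list alone; adjusted p = 3.41e-04, and 0.368 with an estimated correlation).

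Of 20 B-lineage genes at 8wk, 4 rose (4 over the list alone; adjusted p = 0.00230, and 0.464 with an estimated correlation), against 2 without the 3 libraries that stand apart (0.0431). Bach2 rose by 1.73 ± 0.45 log2 (SE, n = 4 per group) and Rag1 by 1.72 ± 0.46 log2. Of 15 Lymphoid-primed progenitor genes 5 rose (6 over the list alone; adjusted p = 0.0255, and 0.368 with an estimated correlation), with Satb1 at 1.50 ± 0.21 log2. That list's adjusted p was 0.144 without 8wk_ME replicate 4, 0.0503 without 8wk_Control replicate 2 and 0.147 without the 3 libraries. Of 13 Immediate early and heat shock genes 5 rose and 1 fell (8 and 2 over the list alone; adjusted p = 0.0331, and 0.368 with an estimated correlation), with the transcription factors Egr1 at 1.39 ± 0.27 log2 and Jun at 2.07 ± 0.48 log2, and the chaperone Hsph1 lower at -0.70 ± 0.16 log2. That call was lost without 8wk_ME replicate 1 (0.0982), without 8wk_Control replicate 3 (0.0579), with at least 1 CPM in 4 libraries (0.0570), with protein-coding genes only (0.0908) and with only the 8wk libraries (0.0574).

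The other lists were not called at 8wk. Polycomb genes (6 of 16 higher, 2 lower; Bmi1 1.58 ± 0.23 log2, SE, n = 4 per group, Ezh2 -0.38 ± 0.08 log2) had an adjusted p of 0.0596. They were called higher with DESeq2 size factors (0.0479), library size only (0.0366), no filter (0.0378), the Y-linked covariate (0.0405) or only the 2 groups (0.0240) or without 8wk_ME replicate 1 (0.0333) or 8wk_Control replicate 3 (0.0463). The adjusted p was 0.940 for HSC markers (1 of 16 higher, 3 lower; median above and mean below 0), 0.232 for Hoxb genes (0 of 5) and 0.0975 for Endothelial markers (3 of 9 higher). The Endothelial markers were called with no filter (0.0193) and without 8wk_Control replicate 1 (0.0305). T and NK cell markers (4 of 14 higher, 1 lower) had 0.177, called with no filter (0.0189) and with only the 8wk libraries (0.0385). Erythroid genes (1 of 18 lower) had 0.546; without the 3 libraries that stand apart 9 rose and 1 fell (0.0131). The adjusted p was 0.326 for Megakaryocyte genes (2 of 12 lower), 0.215 for Mast cell, basophil and eosinophil markers (2 of 13 lower), 0.285 for Fetal progenitor genes (1 of 14 higher, 3 lower), 0.736 for Hepatocyte markers (0 of 3) and 0.744 for Stromal markers (0 of 5).

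**Figure D3:**
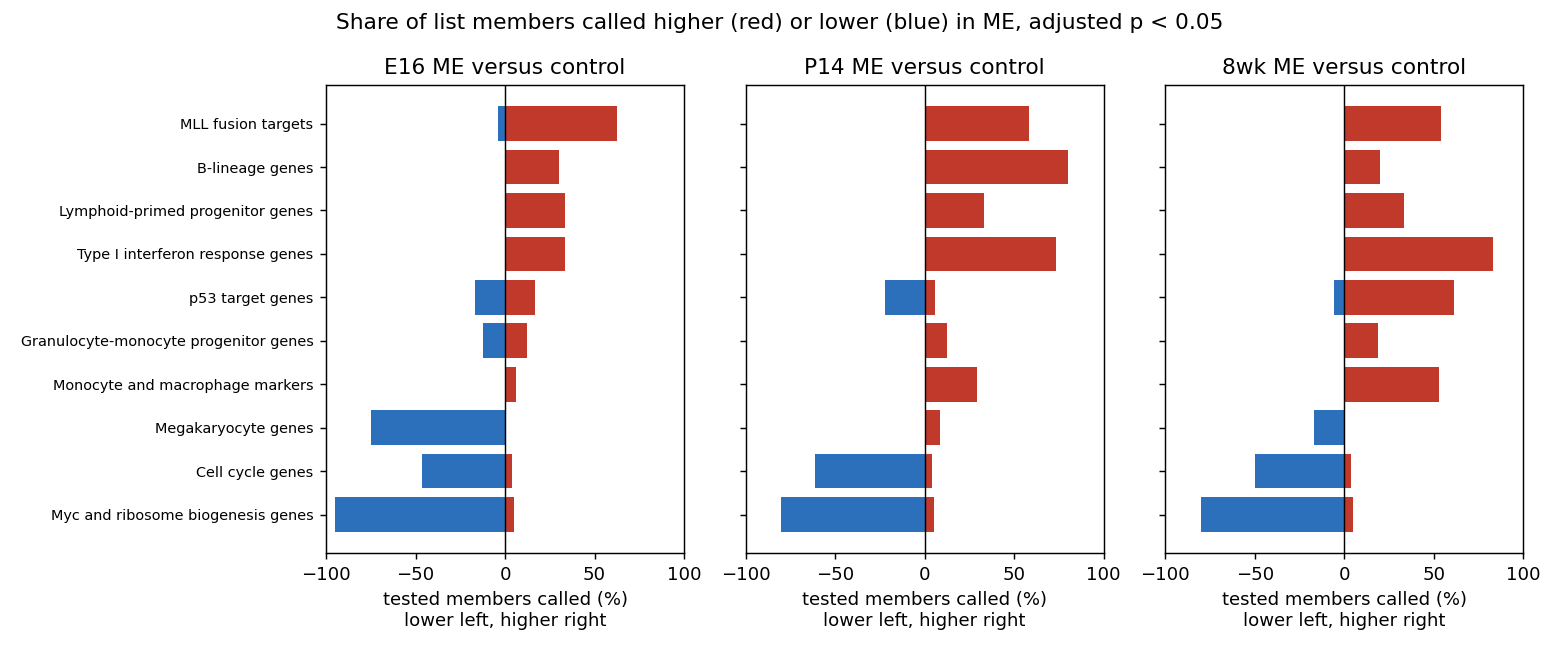
Percent of the tested members of 10 gene lists called higher (red, to the right) or lower (blue, to the left) in ME at each age.

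The ME effects of the 3 ages overlapped. Of 8030 genes called at any age, 1970 were called at all 3, with 1266 higher, 692 lower and 12 of mixed direction. At E16 and P14, 1656 genes were higher at both ages, where 319 would be for independent lists, and 1036 were lower, where 150 would be (149.9). At P14 and 8wk, 1566 were higher (340.0 for independent lists) and 953 lower (253). At E16 and 8wk, 1433 were higher (358 for independent lists) and 911 lower (229). Genes called in opposite directions numbered 1, 23 and 46 for these pairs. Across genes, which are not independent replicates, log2 fold changes correlated at Pearson r = 0.664 and Spearman rho = 0.655 for E16 and P14, 0.646 and 0.591 for P14 and 8wk, and 0.534 and 0.515 for E16 and 8wk.

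The difference of ME effects between P14 and E16 asked whether neonatal and fetal cells responded differently. Skida1 differed by -0.10 ± 0.41 log2 (SE, n = 4 per group; edgeR adjusted p = 1.00) and was not called. Of all genes 4 were called: Alox12, the platelet lipoxygenase, at 4.32 ± 0.56 log2 (adjusted p = 0.00191), Kynu, an enzyme of tryptophan breakdown, at 2.19 ± 0.37, Ifi27, an interferon-induced gene, at 1.81 ± 0.30, and Crispld1, a secreted protein gene, at -1.77 ± 0.28. Alox12 fell in ME at E16 from 31 ± 19.4 CPM and stood at 0.982 ± 0.139 CPM in P14 controls. The calls of Kynu and Ifi27 were lost with the replicate block (adjusted p = 0.248 and 0.106), and 2 genes were then called. DESeq2 called 29 genes and limma-voom 13, and 888 genes had an unadjusted edgeR p under 0.05. The count ranged from 1 to 5 on leaving out 1 library.

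Of 24 lists 10 were called in the difference P14 minus E16 with the preset correlation and 0 with an estimated one (camera), while edgeR called 0 members of each. Higher were Megakaryocyte genes (5 of 12 over the list alone; adjusted p = 1.23e-12) and Type I interferon response genes (10 of 30; 8.92e-14). So were Monocyte and macrophage markers (9.60e-08) and Dendritic cell and MHC class II genes (4.42e-04). Mast cell, basophil and eosinophil markers were higher (9.58e-04), but not without P14_ME replicate 2 (0.0523). With an estimated correlation these lists had, in order, 0.148, 0.385, 0.435, 0.435 and 0.591. Megakaryocyte genes fell in ME at E16 and were not called at P14, where controls already stood lower. HSC markers were lower (0.0122, and 0.591 with an estimated correlation), but not with the Y-linked covariate (0.166) or without E16_ME replicate 4 (0.552) or the 3 libraries that stand apart (0.550).

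B-lineage genes were also higher in the difference P14 minus E16 (adjusted p = 0.0398, and 0.661 with an estimated correlation), but not with at least 1 CPM in 4 libraries (0.0753) or without E16_ME replicates 1 and 4 (0.128 and 0.260), E16_Control replicates 1 and 3 (0.0817 and 0.0598), P14_ME replicates 1 and 2 (0.664 in the other direction and 0.285), P14_Control replicates 3 and 4 (0.0528 and 0.101) or the 3 libraries that stand apart (0.374). Mature neutrophil markers were higher (0.0122, and 0.591 with an estimated correlation), but not with the Y-linked covariate (0.137) or without E16_ME replicate 4 (0.206), E16_Control replicate 1 (0.145), P14_ME replicates 1 and 2 (0.0718 and 0.0973) or P14_Control replicates 3 and 4 (0.0976 and 0.0858). Hoxb genes were lower (0.0310, and 0.244 with an estimated correlation), but not with at least 1 CPM in 4 libraries (0.180) or the Y-linked covariate (0.137) or without E16_ME replicates 1, 3 and 4 (0.0705, 0.0572 and 0.123), E16_Control replicates 1, 3 and 4 (0.0711, 0.133 and 0.0532), P14_ME replicates 3 and 4 (0.0839 and 0.0527), P14_Control replicates 1, 2 and 4 (0.231, 0.0708 and 0.0856) or the 3 libraries that stand apart (0.0640). Cell cycle genes were lower (0.0443, and 0.591 with an estimated correlation), but not with the Y-linked covariate (0.0518) or the replicate block (0.0582) or without E16_ME replicates 1, 2 and 3 (0.128, 0.121 and 0.239), E16_Control replicates 3 and 4 (0.106 and 0.0572), P14_ME replicates 2 and 4 (0.0799 and 0.163) or P14_Control replicates 3 and 4 (0.0976 and 0.184). Granulocyte-monocyte progenitor genes (0.120) were called higher with the replicate block (0.0445) or without E16_ME replicates 2 and 3 (0.0453 and 0.0245), E16_Control replicate 4 (0.0443), P14_ME replicates 3 and 4 (0.0263 and 5.41e-04) or P14_Control replicates 1 and 2 (0.0336 and 0.0202). Erythroid genes (0.116) were called higher with the replicate block (0.0322) or without E16_ME replicate 2 (0.0485), P14_ME replicate 3 (0.0263) or P14_Control replicate 1 (0.0131). Sex-linked genes (0.159) were called higher with the replicate block (0.0445) or protein-coding genes only (0.0329) or without E16_ME replicate 2 (0.0453), P14_ME replicate 1 (0.0424) or P14_Control replicate 4 (0.00114).

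The difference between 8wk and P14 asked whether adult cells responded as neonatal ones did. The ME effect on Skida1 differed by -1.99 ± 0.41 log2, a smaller rise at 8wk (SE, n = 4 per group; edgeR adjusted p = 0.0376). Pmaip1 (2.62 ± 0.52 log2) and Bax (0.95 ± 0.15), which promote apoptosis, had more positive ME effects at 8wk. Bax fell at P14 (-0.59 ± 0.10) and rose at 8wk (0.36 ± 0.10), and Pmaip1 was not called at P14 (-0.60 ± 0.37) and rose at 8wk (2.02 ± 0.38). Hoxa10 (-1.26 ± 0.21) rose less at 8wk. Cttnbp2nl was at 2.60 ± 0.53, and Ncf1, a subunit of the phagocyte oxidase, at 1.59 ± 0.30. In all 57 genes were called, 37 higher and 20 lower, but 2 with the replicate block, of which 0 were among the 57. The call of Skida1 was lost with the block (adjusted p = 0.166) and without P14_ME replicates 1, 2, 3 or 4 (0.0609, 0.0669, 0.0616 and 0.0674), P14_Control replicates 1, 2 or 3 (0.0700, 0.0855 and 0.0770), 8wk_ME replicates 1, 2 or 3 (0.0646, 0.0898 and 0.0933) or 8wk_Control replicates 2 or 3 (0.111 and 0.0764). DESeq2 called 298 genes, limma-voom 552, and 2202 had an unadjusted edgeR p under 0.05. The count was 4 without P14_ME replicate 4, 369 without 8wk_Control replicate 1 and 1009 without the 3 libraries that stand apart, which kept all 57.

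Of 24 lists 7 were called in the difference 8wk minus P14. The p53 target genes were higher (2 of 18 members, 9 over the list alone; camera adjusted p = 4.25e-14, and 0.0497 with an estimated correlation), 10 without the 3 libraries that stand apart. The other calls were lost with an estimated correlation. Mature neutrophil markers (adjusted p = 3.67e-06, and 0.721 with an estimated correlation) and Granulocyte-monocyte progenitor genes (1.20e-05, and 0.721 with an estimated correlation) were higher with 0 members called by edgeR. MLL fusion targets were lower (Hoxa10 and Skida1 of 24, 3 over the list alone; 0.00229, and 0.721 with an estimated correlation), but not without 8wk_ME replicate 1 (0.0591). Monocyte and macrophage markers (0.0361; median above and mean below 0) and Dendritic cell and MHC class II genes (0.0361) were higher, and HSC markers lower (0.0361). With an estimated correlation their adjusted p was 0.772, 0.721 and 0.772. The Monocyte and macrophage markers were not called with DESeq2 size factors (0.0634) or without P14_ME replicates 3 and 4 (0.153 and 0.130), P14_Control replicates 1 and 2 (0.174 and 0.180), 8wk_ME replicates 1, 2 and 3 (0.100, 0.120 and 0.0555) or 8wk_Control replicates 2, 3 and 4 (0.120, 0.415 and 0.115). The Dendritic cell and MHC class II genes were not called with at least 1 CPM in 4 libraries (0.0993) or without P14_ME replicates 3 and 4 (0.116 and 0.117), P14_Control replicates 1 and 2 (0.151 and 0.0979), 8wk_ME replicate 2 (0.120) or 8wk_Control replicates 2, 3 and 4 (0.0661, 0.178 and 0.0794). The HSC markers were not called with library size only (0.0650) or at least 1 CPM in 4 libraries (0.0507) or without P14_ME replicates 2 and 3 (0.0576 and 0.0599), P14_Control replicate 2 (0.0984), 8wk_ME replicates 1 and 2 (0.591 and 0.120) or 8wk_Control replicates 1 and 4 (0.168 and 0.0589).

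The difference between 8wk and E16 asked whether adult cells responded as fetal ones did. The ME effect on Skida1 differed by -2.09 ± 0.41 log2, a smaller rise at 8wk (SE, n = 4 per group; edgeR adjusted p = 0.0170), while Mllt1 differed by -0.06 ± 0.40 and Kmt2a by -0.12 ± 0.32 log2, not called. Hoxa10 (-1.15 ± 0.21 log2) and the RNA-binding protein gene Lin28b (-2.01 ± 0.38) also had more negative ME effects at 8wk, as did Crispld1 (-2.21 ± 0.28; adjusted p = 4.65e-04). ME effects were more positive at 8wk for Thbs1, thrombospondin (6.63 ± 1.18), the chemokine gene Cxcl10 (4.98 ± 0.98) and Pmaip1 (2.82 ± 0.52). Jchain, the immunoglobulin joining chain, was at 5.35 ± 1.14, with 154 CPM in 8wk_ME replicate 4 and 7.13 to 9.09 in the other 8wk ME libraries. In all 161 genes were called, 87 higher and 74 lower. Without 8wk_Control replicate 2 the Skida1 call was lost (adjusted p = 0.0511) and the count was 48. It was 896 without 8wk_Control replicate 1, and 1362 without the 3 libraries that stand apart, 159 of them among the 161. It was 603 with DESeq2, 1583 with limma-voom and 59 with the Y-linked covariate.

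Of 24 lists 12 were called in the difference 8wk minus E16, and 0 with an estimated correlation; 4 p53 target genes (9 over the list alone; camera adjusted p = 2.52e-10, and 0.104 with an estimated correlation) were higher. MLL fusion targets were lower (3 of 24, 5 over the list alone; 4.50e-04). So were HSC markers (Hoxb5 of 16; 2.90e-05) and Hoxb genes (Hoxb5 of 5; 0.00729). In this order they had 0.206, 0.248 and 0.104 with an estimated correlation. Higher with 0 members called by edgeR were Mature neutrophil markers (2.03e-10), Monocyte and macrophage markers (2.52e-10), Type I interferon response genes (1.17e-09), Granulocyte-monocyte progenitor genes (4.02e-08), Megakaryocyte genes (1.68e-07) and Dendritic cell and MHC class II genes (2.80e-07). With an estimated correlation they had 0.177, but 0.244 for interferon and 0.220 for granulocyte-monocyte genes. Megakaryocyte genes fell at E16 and were not called at 8wk. Without the 3 libraries that stand apart, 11 Type I interferon response genes and 9 p53 target genes were called. 

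T and NK cell markers were higher in the difference 8wk minus E16 (0 of 14 called by edgeR, 2 over the list alone; camera adjusted p = 0.0394, and 0.184 with an estimated correlation), but not with DESeq2 size factors (0.0510), at least 1 CPM in 4 libraries (0.577) or the Y-linked covariate (0.0713) or without E16_ME replicates 1 and 2 (0.0568 and 0.0585), E16_Control replicate 2 (0.133), 8wk_ME replicates 2 and 3 (0.0732 and 0.0830) or 8wk_Control replicates 2 and 4 (0.0877 and 0.0650). Immediate early and heat shock genes were higher (0 of 13 called by edgeR; 0.0206, and 0.263 with an estimated correlation), but not with at least 1 CPM in 4 libraries (0.0809) or without 8wk_ME replicate 1 (0.0901) or 8wk_Control replicate 3 (0.0646). Erythroid genes (0.0552) were called higher with library size only (0.0328), no filter (0.0254), at least 1 CPM in 4 libraries (0.0488) or the Y-linked covariate (0.0328) or without E16_ME replicates 1 and 2 (0.0244 and 0.0291), E16_Control replicates 1 and 2 (0.0439 and 0.0283), 8wk_ME replicate 4 (0.0372), 8wk_Control replicate 1 (7.67e-04) or the 3 libraries that stand apart (7.16e-05).

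The controls were compared between ages for the background against which ME acted. From E16 to P14, Dntt, the lymphoid enzyme TdT, rose from 0.895 ± 0.252 to 60.1 ± 28.0 CPM (SD, n = 4 per group), a log2 fold change of 6.09 ± 0.48 (SE; edgeR adjusted p = 2.19e-08). Igf2bp1 and Lin28b, RNA-binding proteins of fetal cells, fell at -6.99 ± 0.32 and -2.37 ± 0.25 log2. C1qa, a macrophage complement gene, had 0 counts at P14 and was at least 619-fold lower. Skida1 differed by -0.66 ± 0.30 log2 (adjusted p = 0.156) and was not called at any pair of control ages. In all 1441 genes were higher and 1421 lower at P14.

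All 30 Type I interferon response genes fell from E16 to P14 (30 over the list alone; camera adjusted p = 2.51e-109, and 1.65e-04 with an estimated correlation), Rsad2 at -5.42 ± 0.35 log2 (SE, n = 4 per group). Of 14 Fetal progenitor genes 10 fell and Cdkn1c rose (10 and 1 over the list alone; 2.58e-21, and 2.71e-06 with an estimated correlation). The falls in the following lists were not called with an estimated correlation. All 17 Monocyte and macrophage markers fell (17 over the list alone; 6.38e-16, and 0.0822 with an estimated correlation), as did 13 of 14 Mature neutrophil markers (14 over the list alone; 4.40e-09, and 0.213 with an estimated correlation), the granule gene Camp at -8.52 ± 1.70 log2. Of 13 Dendritic cell and MHC class II genes 11 fell and H2-DMa rose (11 and 1 over the list alone; 4.62e-09, and 0.0822 with an estimated correlation), and of 12 Megakaryocyte genes 9 fell (10 over the list alone; 8.65e-09, and 0.0889 with an estimated correlation). Of 18 Erythroid genes 9 fell, Hbb-bs at -4.08 ± 0.65 log2, and Car2 rose by 1.19 ± 0.13 log2 (10 and 1 over the list alone; 1.35e-04, and 0.213 with an estimated correlation). Also lower were Granulocyte-monocyte progenitor genes (6 of 16, 9 over the list alone; 6.94e-05, and 0.391 with an estimated correlation), B-lineage genes (6 of 20, 7 over the list alone, while Cd72 rose; 0.00115, and 0.452 with an estimated correlation) and Mast cell, basophil and eosinophil markers (4 of 13, 6 over the list alone; 0.00713, and 0.452 with an estimated correlation). So were p53 target genes (5 of 18, 5 over the list alone; 6.89e-04, and 0.298 with an estimated correlation) and Immediate early and heat shock genes (5 of 13, 7 over the list alone; 0.00524, and 0.219 with an estimated correlation). MLL fusion targets were higher (7 of 24, with Hoxa7 lower, and 9 and 2 over the list alone; 0.00984, and 0.371 with an estimated correlation). Of 3 Hepatocyte markers Trf and Afp rose (2 over the list alone; 0.00282, and 0.0355 with an estimated correlation), a call lost with no filter (0.283 in the other direction) or without E16_Control replicates 1, 2 and 3 (0.162, 0.166 and 0.151), P14_Control replicates 1 and 2 (0.0589 and 0.127) or the 3 libraries that stand apart (0.0755).

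From P14 to 8wk controls, Igf2bp3, an RNA-binding protein of fetal cells, fell from 69.6 ± 3.71 to 0.993 ± 0.244 CPM (SD, n = 4), a log2 fold change of -6.15 ± 0.23 (SE; edgeR adjusted p = 1.78e-14), and Lin28b fell at -2.75 ± 0.27 log2. The MHC class I genes H2-Q7 and H2-Q6 rose by 4.04 ± 0.50 and 3.86 ± 0.45 log2, and the immunoglobulin gene Igkc by 6.54 ± 1.21 log2. Of 14 Fetal progenitor genes 8 fell (8 over the list alone; camera adjusted p = 2.83e-27, and 4.05e-07 with an estimated correlation). Of 30 Type I interferon response genes 20 rose (24 over the list alone; 5.43e-22, and 0.186 with an estimated correlation), Usp18 by 2.46 ± 0.36 log2. In all 1327 genes were higher and 1057 lower at 8wk. The total of 2384 became 929 without P14_Control replicate 3, 989 without 8wk_Control replicate 3, 1505 without 8wk_Control replicate 2 and 3605 without the 3 libraries that stand apart.

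Myeloid and megakaryocyte lists were higher in 8wk than in P14 controls, and each call was lost without 8wk_Control replicate 1. Its Lcn2, a neutrophil granule gene, stood at 27.6 CPM against 0.733 to 0.837 in the other 8wk controls. Mature neutrophil markers (5 of 14, 11 over the list alone; camera adjusted p = 0.0133, and 0.759 with an estimated correlation) were not called without 8wk_Control replicate 1 (0.259). Megakaryocyte genes (3 of 12, 8 over the list alone; 0.00738, and 0.683 with an estimated correlation) were not called without 8wk_Control replicate 1 (0.163) or the 3 libraries that stand apart (0.180). Dendritic cell and MHC class II genes (6 of 13, 7 over the list alone; 0.0145, and 0.683 with an estimated correlation) were not called without 8wk_Control replicate 1 (0.224). Mast cell, basophil and eosinophil markers (3 of 13, 3 over the list alone; 0.0133, and 0.690 with an estimated correlation) were not called with at least 1 CPM in 4 libraries (0.0659) or without P14_Control replicate 4 (0.105) or 8wk_Control replicate 1 (0.163). Monocyte and macrophage markers (2 of 17, 2 over the list alone; 0.0422, and 0.769 with an estimated correlation) were not called with at least 1 CPM in 4 libraries (0.0627), the Y-linked covariate (0.0725) or protein-coding genes only (0.0673) or without P14_Control replicates 3 and 4 (0.0999 and 0.105) or 8wk_Control replicate 1 (0.738). Lymphoid-primed progenitor genes were lower (4 of 15, 5 over the list alone, with Dntt among the members higher; 0.0480, and 0.683 with an estimated correlation; median below and mean above 0), but not with DESeq2 size factors (0.0521), library size only (0.0668), at least 1 CPM in 4 libraries (0.0762), the Y-linked covariate (0.0725) or protein-coding genes only (0.203) or without P14_Control replicates 1 and 3 (0.0579 and 0.0999) or 8wk_Control replicates 1, 2, 3 and 4 (0.0647, 0.126, 0.0893 and 0.0591). Of 3 Hepatocyte markers Afp rose (0.0422, and 0.186 with an estimated correlation), a list not called with no filter (0.0850), at least 1 CPM in 4 libraries (0.0659) or protein-coding genes only (0.0673) or without P14_Control replicates 1, 2, 3 and 4 (0.0785, 0.121, 0.287 and 0.109), 8wk_Control replicates 1, 2, 3 and 4 (0.224, 0.183, 0.124 and 0.129) or the 3 libraries that stand apart (0.185).

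From E16 to 8wk controls, Dntt rose by 7.24 ± 0.50 log2 (SE, n = 4 per group; edgeR adjusted p = 2.43e-09) and Crispld1 by 4.55 ± 0.23 log2. Igf2bp3 fell from 134 ± 7.22 to 0.993 ± 0.244 CPM (SD), -7.09 ± 0.23 log2, and Lin28b fell at -5.12 ± 0.29 log2. Of 14 Fetal progenitor genes 11 fell (12 over the list alone; camera adjusted p = 1.52e-52, and 1.88e-09 with an estimated correlation). All 30 Type I interferon response genes fell (30 over the list alone; 2.86e-46, and 0.00911 with an estimated correlation). Of 3 Hepatocyte markers Trf and Afp rose (3.96e-05, 0.00296 with an estimated correlation, and 0.958 with no filter). The following were lower and not called with an estimated correlation. They were Monocyte and macrophage markers (12 of 17, 13 over the list alone; 2.11e-08, and 0.228 with an estimated correlation), Lymphoid-primed progenitor genes (7 of 15, 10 over the list alone, with Dntt higher; 7.46e-04, and 0.228 with an estimated correlation), Erythroid genes (9 of 18, 10 over the list alone, with Car2 higher; 7.46e-04, and 0.228 with an estimated correlation) and Mature neutrophil markers (4 of 14, 6 over the list alone; 7.46e-04, and 0.446 with an estimated correlation). They were also Megakaryocyte genes (7 of 12, 8 over the list alone; 0.00444, and 0.396 with an estimated correlation), Dendritic cell and MHC class II genes (8 of 13, 9 over the list alone, with H2-DMa higher; 5.79e-04, and 0.228 with an estimated correlation), p53 target genes (8 of 18, 9 over the list alone; 4.32e-04, and 0.228 with an estimated correlation) and Immediate early and heat shock genes (7 of 13, 7 over the list alone; 0.00485, and 0.228 with an estimated correlation). Granulocyte-monocyte progenitor genes (0 of 16 called by edgeR; 0.0310, and 0.636 with an estimated correlation) were not called with protein-coding genes only (0.0531) or without E16_Control replicate 1 (0.0573) or 8wk_Control replicates 2, 3 and 4 (0.0699, 0.0681 and 0.0505). B-lineage genes (4 of 20, 5 over the list alone, with Cd72 higher; 0.0311, and 0.636 with an estimated correlation) were not called with at least 1 CPM in 4 libraries (0.0699) or protein-coding genes only (0.156) or without 8wk_Control replicates 2 and 4 (0.0760 and 0.0505) or the 3 libraries that stand apart (0.0825). In all 2372 genes were higher and 2046 lower at 8wk.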

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

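The library splits were planned, and the GC, unspliced RNA, fusion transcript, left-out library, Alb and progenitor share tests and the exchange of residuals were chosen only after the results were seen. With libraries exchanged between the groups, only the real grouping, 1 of 35 splits, gave so high an edgeR count in each of 6 comparisons. This share is the smallest that 35 splits can give and lies under the planned limit of 0.05. A random grouping of these libraries is thus an unlikely source for ME at E16 and 8wk and for the control ages. If replicates were not separate animals, the splits speak only for these libraries. At P14, where replicate numbers may pair ME and control libraries, the 8 splits that part all pairs are too few for a share under 0.05. Their real count was 4168 and the highest other 0, while splits that keep some pairs together reached 100. The real and highest other counts were 4125 and 0 for ME at E16 and 5392 and 3136 at 8wk. For the controls they were 2862 and 376 for P14 against E16, 2384 and 928 for 8wk against P14, and 4418 and 506 for 8wk against E16. The 8wk split with 3136 genes exchanged 8wk_ME replicate 4 with 8wk_Control replicate 1, the libraries that stand apart at that age, which points to a structure of the samples beyond the groups. For differences of ME effects, residuals were exchanged 100 times (the real order included) and counted with limma-trend, which calls other numbers of genes than edgeR. For 8wk minus E16 the real order gave the highest count (63 genes, 1 of 100, highest other 1), so a random order of these libraries is an unlikely source. For P14 minus E16 the real order was also the highest (5 genes, 1 of 100, highest other 1), but the exchange left out any pairing at P14, and edgeR called 2 genes with the replicate block and 1 with the Y-linked covariate. For 8wk minus P14 limma-trend called 0 genes, so the exchange (100 of 100, highest other 10) decides nothing, against 57 with edgeR, 298 with DESeq2, 552 with limma-voom and 2202 at an unadjusted edgeR p under 0.05.

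A first pattern is that 1266 genes were higher in ME at all 3 ages. After GC correction, with the replicate block at P14, 985 of these were still called higher at all ages (77.8%), and 1029 without the block, so GC content does not account for them as a set. Reads from outside spliced genes, from unspliced RNA or DNA, would also raise TEC and antisense genes. The 1198 such genes tested had medians of 0.50, 0.34 and 0.12 log2 at E16, P14 and 8wk, against 1.72, 1.83 and 1.65 for the 1266 genes. These medians cannot decide, since the 1266 genes were chosen for their rise in these data and the 1198 were not. A response to MLL::ENL stays open as a hypothesis, and so does some unspliced RNA, since 160 of the 1198 were called higher at E16 and 3 lower.

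A second pattern is the smaller rise of Skida1 at 8wk (8wk minus E16 -2.09 log2, and 8wk minus P14 -1.99, not called with the replicate block, adjusted p = 0.166). Less fusion transcript at 8wk would lower the excess of Mllt1 in ME over control, but its ratio of 8wk to E16 was 0.888 (95% bootstrap interval 0.597 to 1.30), against 0.126 for the Skida1 excess. Without 8wk_ME replicate 4 the Skida1 difference was -2.05 ± 0.43 log2 (SE; adjusted p = 0.00995), and after GC correction -2.04 ± 0.41 (adjusted p = 0.0143), where the adjusted p over all alternatives ran from 2.56e-04 to 0.0511, the latter without 8wk_Control replicate 2. An age difference in how the Skida1 locus responds may be the source and was not tested, and age and tissue cannot be separated against E16. Mllt1 counts hold endogenous reads too, so this measures the fusion only through its excess.

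The last pattern weighed is that markers of mature cells were lower in P14 than in E16 controls, where E16 cells came from liver. Hepatocyte RNA would bring Alb, which reached 0.0675 CPM at most in an E16 control library and 52 counts over all 24 libraries; 12 of 15 Hepatocyte markers were too low to test. A lower share of progenitors at E16 would raise markers of other lineages, though not by equal log2 amounts. The medians of all 8 lists of mature cells with 10 or more tested members were below 0 at P14, so a first criterion against it, that some list be unchanged or higher, was not met as judged by medians, though T and NK cell markers were not called (0.588). A second criterion against it, set after these values were seen, was that the intervals of the lowest and highest median do not overlap. It was met, with medians 5.40 log2 apart, from -6.44 for Mature neutrophil markers (95% interval -8.11 to -4.91) to -1.04 for T and NK cell markers (-3.58 to 0.59). This gap cannot decide, since the rise of a marker also depends on its level in progenitors and on the mix of other cells. A lower share of progenitors therefore stays open. Differentiation during 48 h of culture, tissue and age stay open too and were untested, and the LSK sort would remove mature cells present at the start of culture.

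Some libraries lay far from the others of their group. The 10 most abundant genes took 4.90% of counts in E16_ME replicate 1, 8.29% in E16_Control replicate 4 and 4.93% in P14_Control replicate 4. Ribosomal RNA took 2.03% in E16_ME replicate 1, 5.09% in E16_Control replicate 4 and 1.38% in 8wk_ME replicate 2. Mllt1 was at 9.90 CPM in 8wk_Control replicate 3, and the first principal component was at 10.8 in 8wk_Control replicate 1. Values of named genes lay apart 31 times in E16_ME replicate 4, 46 times in 8wk_Control replicate 1, 14 in 8wk_ME replicate 4, 10 in E16_Control replicate 1, 10 in P14_Control replicate 2, 8 in P14_ME replicate 3, 8 in P14_Control replicate 1 and 7 in P14_ME replicate 4. In all 177 of 1590 gene and group pairs did so (11.1%). Chance gives about 1 in 20 for normally distributed values, which CPM need not be, so this share does not measure an excess.

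These ME effects were called as different between ages by an interaction test of edgeR without the replicate block, in log2. With the block, which takes libraries of equal number as pairs, Kynu (adjusted p = 0.248) and Ifi27 (0.106) were not called for P14 minus E16. For 8wk minus P14, 0 of the 57 genes were called with it. P14 minus E16 had 4 genes called, Alox12 at 4.32, Kynu at 2.19, Ifi27 at 1.81 and Crispld1 at -1.77, and 10 lists. For 8wk minus P14, with 57 genes and 7 lists, the named genes above 0 were Pmaip1 at 2.62, Cttnbp2nl at 2.60, Spint1 at 1.71, Upp1 at 1.66, Ncf1 at 1.59, Gstm5 at 1.58 and Bax at 0.95. Those below 0 were Skida1 at -1.99, Fam171b at -1.92, St3gal6 at -1.43, Hoxa10 at -1.26, Ikzf2 at -1.19 and Mdp1 at -1.15. For 8wk minus E16, with 161 genes and 12 lists, the named genes above 0 were Thbs1 at 6.63, Jchain at 5.35, Cxcl10 at 4.98, Cox6a2 at 4.22, Cdh2 at 4.04 (on 2 counts in the 8wk controls, with ME at 12.7 ± 2.38 CPM at 8wk and 46.0 ± 11.8 at E16), Tnf at 3.98, Pmaip1 at 2.82, Cdkn1a at 2.69, Sesn2 at 1.22 and Bax at 0.73. Those below 0 were Pcdh7 at -3.06, Lhfp at -2.91, Sox18 at -2.58, Btc at -2.50, Hoxb5 at -2.26, Crispld1 at -2.21, Skida1 at -2.09, Lin28b at -2.01, Hmga2 at -1.16, Hoxa10 at -1.15, Hoxa5 at -1.11 and Ezh2 at -0.46. The alternatives and left-out libraries under which these counts move by over 1.5 times are given with the processing.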

How the results depend on the processing

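Counts of called genes within 1.5 times of the value as designed are not listed, apart from those with the replicate block, and for those below the cause was not tested, except that the limit of 2-fold lowers counts by its construction. With the limit of 2-fold they were 1870, 1828 and 2062 for ME at E16, P14 and 8wk, 35 for 8wk minus P14, and 1583, 469 and 1874 for control P14 against E16, 8wk against P14 and 8wk against E16. With limma-voom they were 6520 for ME at E16, 13 for P14 minus E16, 552 for 8wk minus P14 and 1583 for 8wk minus E16. The DESeq2 Wald test gave 29, 298 and 603 for these 3 differences. The replicate block gave 3189, 3280 and 4333 for ME at E16, P14 and 8wk, 2 for P14 minus E16, 2 for 8wk minus P14 and 173 for 8wk minus E16, and with GC correction 2 and 12 for the first 2 differences. The Y-linked covariate gave 1 for P14 minus E16 and 59 for 8wk minus E16. For 8wk minus E16, no filter gave 107, at least 1 CPM in 4 libraries 250 and protein-coding genes 258. No filter gave 1483 for control 8wk against P14, and only the libraries of the 2 groups 1092, against 2907 for ME at 8wk. Without the 3 libraries that stand apart, chosen after seeing the data, counts were 10 for P14 minus E16, 1009 for 8wk minus P14, 1362 for 8wk minus E16 and 3605 for control 8wk against P14. Library size only moved the median of all genes by 0.11 log2 at E16 and P14, and GC correction by -0.15, -0.16 and -0.17 at the 3 ages, so directions of small changes are relative to these shifts. Under DESeq2 size factors and library size only, no called list changed direction.

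With an estimated correlation, lists called were 4, 3 and 0 for ME at E16, P14 and 8wk, 0, 1 and 0 for P14 minus E16, 8wk minus P14 and 8wk minus E16, and 3, 1 and 3 for the control ages. For P14 minus E16, 6 lists were called with the Y-linked covariate. With the replicate block 9, 11 and 9 of 20 B-lineage genes were higher in ME at E16, P14 and 8wk, against 6, 16 and 4 without it. In comparisons without P14 ME libraries, the block changed these list calls and no others. For 8wk minus E16 it called Erythroid genes (0.00301), Mast cell, basophil and eosinophil markers (0.0117) and Sex-linked genes (0.0263) higher. It called Endothelial markers higher at E16 (0.0305) and Polycomb genes higher at 8wk (0.0298). For control 8wk against P14 it called Granulocyte-monocyte progenitor genes higher (0.0322) and not Hepatocyte markers (0.0521). The correlation of ME effects over genes of at least 1 CPM was 0.811 for E16 and P14, 0.774 for P14 and 8wk, and 0.662 for E16 and 8wk. Leaving out 1 library gave ranges of 0.619 to 0.674, 0.567 to 0.665 and 0.453 to 0.563.

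Leaving out 1 library, counts ranged from 3024 to 3719 for ME at E16, 2875 to 4409 at P14 and 3433 (8wk_Control replicate 3) to 6571 at 8wk. For control ages they ranged from 2091 to 2593, 929 to 3115 and 3333 to 4916. For control 8wk against P14 they were 929 without P14_Control replicate 3, 1505 without 8wk_Control replicate 2 and 989 without 8wk_Control replicate 3. For P14 minus E16 they ranged from 1 to 5, with 1 without E16_ME replicates 3 or 4, E16_Control replicates 1 or 2, or P14_ME replicates 2, 3 or 4, and 2 without E16_ME replicate 1, E16_Control replicate 4 or P14_Control replicate 1. For 8wk minus P14 they ranged from 4 to 369: 12, 8 and 4 without P14_ME replicates 2, 3 and 4, 29, 12 and 14 without P14_Control replicates 2, 3 and 4, 9, 5, 8 and 224 without 8wk_ME replicates 1 to 4, and 369, 5 and 33 without 8wk_Control replicates 1, 2 and 4. For 8wk minus E16 they ranged from 48 to 896: 105 and 87 without E16_ME replicates 1 and 4, 70 and 72 without E16_Control replicates 1 and 2, 72, 94, 104 and 739 without 8wk_ME replicates 1 to 4, and 896, 48, 83 and 103 without 8wk_Control replicates 1 to 4. Lists called ranged from 11 to 13, 5 to 9 and 11 to 13 for ME, 6 to 12, 4 to 7 and 11 to 13 for the differences, and 13 to 15, 3 to 10 and 11 to 14 for control ages. They were 6 for P14 minus E16 without E16_ME replicate 4 or P14_ME replicate 2, 4 for 8wk minus P14 without P14_Control replicate 2 or 8wk_ME replicates 1 or 2, and 3 for control 8wk against P14 without 8wk_Control replicate 1. Of 11198 values of the 267 named genes under these alternatives, 10198 stayed on the same side of the threshold, 997 lost their call, 3 gained 1 (Kmt2a in control 8wk against E16) and 0 reversed. Replicate numbers alone do not pair E16 or 8wk libraries, and at P14 such pairs are possible but not shown. Genes far below 1 CPM rest on few counts, and depth limits folds where a group held 0 counts.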

Other observations

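All tests in this part were chosen only after the results were seen, so each reading is a hypothesis. Genes of glycolysis and hypoxia, a list of 22 written after some of its members had been seen, moved apart with age. They were called lower in ME 13 times at E16 and 14 times at P14, and higher 12 times at 8wk (edgeR). Aldoa, the glycolytic aldolase, was at -0.68 ± 0.14 log2 at E16, -0.54 ± 0.14 at P14 and 0.62 ± 0.14 at 8wk (SE, n = 4 per group), a difference 8wk minus E16 of 1.29 ± 0.20 (adjusted p = 0.00321). Eno1, enolase, differed by 1.19 ± 0.21 log2. Of the 22 genes, 11 were called higher in the difference 8wk minus E16. The list's camera p was 7.68e-30 for 8wk minus E16, and 0.00109 with an estimated correlation, and these are no independent evidence, since the list was chosen from these data. The cause of this change of direction was not tested.

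Some genes near Il9r on chromosome 11 rose with it in ME, and others did not at every age. Of the nearest tested genes on each side, Nsg2 was at 2.35 ± 0.44, 1.70 ± 0.41 and 1.61 ± 0.42 log2 at E16, P14 and 8wk, and Snrnp25 at 0.81 ± 0.15, 0.79 ± 0.15 and 0.66 ± 0.15, called at each age. Rhbdf1, a rhomboid family gene, was at 3.71 ± 0.36, 3.59 ± 0.35 and 2.83 ± 0.34 log2 at E16, P14 and 8wk (SE, n = 4 per group), and Mpg, a DNA repair glycosylase, at 1.36 ± 0.11, 1.39 ± 0.11 and 1.30 ± 0.11. Nprl3, which overlaps Mpg, was not called at E16 (0.20 ± 0.12) or P14 (0.19 ± 0.12) and was at 0.53 ± 0.12 at 8wk. Cpeb4, beyond Nsg2, was not called at E16 (0.18 ± 0.18) or P14 (0.29 ± 0.19) and was at 0.99 ± 0.19 at 8wk, and Bod1, farther still, was at 3.17 ± 0.34, 3.35 ± 0.34 and 2.93 ± 0.33. The nearby alpha globin genes Hba-a1 and Hba-a2 were not called. Over the genome, 64 of 10378 adjacent pairs were higher together at all 3 ages, against a mean of 46.3, a 95th percentile of 57 and a highest of 67 in 1000 random orders. Neighbouring genes may therefore rise together more than by chance, but this region was picked from a scan of the genome, and overlapping reads (Mpg overlaps Nprl3) were not excluded.

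The libraries 8wk_ME replicate 4 and 8wk_Control replicate 1 stand apart, and exchanged labels might explain this. For 4 of 4 genes, Skida1, Il9r, Cdh2 and Nkx2-3, both libraries lay at the level of their labels, for example Il9r at 32.3 CPM in 8wk_ME replicate 4 and 0.223 in 8wk_Control replicate 1, which argues against it. Markers of myeloid cells set them apart: Lcn2 was at 1.69 CPM in 8wk_ME replicate 4, against 43.0 to 83.2 in the other 8wk ME libraries, and Camp at 38.7 CPM in 8wk_Control replicate 1. In E16_ME replicate 4, Lcn2 was at 0.851 CPM, against 19.8 to 33.3 in the other E16 ME libraries.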
